A study of Arabidopsis thaliana with 14 samples.

How the data were processed

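RNA was sequenced from 1 g of seedling tissue, grown for 11 days under 16 h light at 23 °C and 8 h dark at 21 °C, as single ends of 50 nt. The selection of RNA, the strand and the library kit are not given in the sources used here. The 14 libraries form 7 groups of 2: Col-0, fve and suvh2/9 in the first deposited table, and Col-0, rrm1, pdp1/2/3 and the quadruple mutant pdp1/2/3;rrm1 in the second. The processing notes of the authors name HISAT2, featureCounts, edgeR and TAIR10, without versions or the role of each. The deposited values are a normalised signal per gene and library, which the authors do not define further. They have the form of edgeR pseudo-counts, that is counts adjusted to a common library size: between 0.5 and 10, at least 99.8% of the values lay within 0.2 of a whole number in 12 libraries, but 72.8% in rrm1 replicate 1 and 90.0% in quadruple-mutant replicate 1. Whole read counts could not be recovered from them, so tests on reads (edgeR, DESeq2) were not run. All 32548 gene identifiers of both tables matched the reference annotation (TAIR10.1, a build that may differ from that of the authors), 27444 of them protein-coding and 3480 long non-coding. Transposable element genes are not in the tables and were not analysed here.

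Values were divided by the common total of their table (21485094 adjusted counts in the first, 19220337 in the second) and multiplied by 1e+06, giving adjusted counts per 1e+06 (CPM). Library totals were 21259805 to 21722950 and 18609045 to 19534578, and the 10 most abundant genes took 8.02% to 8.65% of a library. At these totals 1 count is 0.0465 or 0.0520 CPM and the level that a count of 0 allows, taken as 3 counts per library, is 0.140 or 0.156; both cover counting error only. Between replicates the chi-square per gene was 2.79 to 6.99, above the value of 1 that counting error alone would give. Genes with at least 1 CPM in at least 2 libraries of a table were tested, 19090 in the first and 19241 in the second, of which 18810 in both.

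Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on log2 of the level plus 1, with 1 fit per table over all its groups. Residual degrees of freedom were 3 and 4 and prior degrees of freedom 8.50 and 7.82. The 9 comparisons were fve, suvh2/9, rrm1, pdp1/2/3 and the quadruple mutant against the Col-0 of their table, fve against suvh2/9, the quadruple mutant against pdp1/2/3 and against rrm1, and the interaction of rrm1 and pdp1/2/3. No comparison between libraries of different tables was tested. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Where a 2-fold minimum is given, it applies to the level plus 1 and not to the level itself. In simulated data every gene of a table had the same dispersion, the median within groups over all groups of that table (0.00102 and 0.00161). Genes that were changed had a mean of at least 2 CPM. With the dispersion of the first table this recovered 92% of 50 genes changed 1.5-fold and 100% at 2-, 4- and 8-fold, with 2.97% of calls false. With that of the second table it recovered 82% and 100%, with 5.45% false. Spread that differs between genes or libraries was not simulated, so these rates need not hold for the data.

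Genes to be named were chosen by a rule fixed, like the groups, comparisons, lists and most alternatives, before the data were examined. The rule named the genes listed as mutated; FLC, FT, SOC1, SDC, FWA and ROS1; for each mutant against Col-0 the 5 called genes with the highest and the 5 with the lowest log2 difference (3 and 3 between mutants) among those with a mean of at least 5 CPM and both libraries of one group above both of the other; and up to 3 called members of each list with the smallest p. It gave 252 tested gene and comparison pairs, and 35 more, such as the touch genes and AT1G64795 in the second table, were added after their values were seen. Gene lists, 21 in number, covered the FLC clade, floral promoters, floral repressors outside the FLC clade, the autonomous pathway, cold-regulated genes, the RNA-directed DNA methylation machinery, methylation maintenance and demethylation, genes silenced by DNA methylation, Polycomb Repressive Complex 2 subunits and partners, developmental Polycomb targets, photosynthesis, the circadian clock, salicylic acid and immune response, jasmonate response, anthocyanin and flavonoid synthesis, heat shock, cell division, root markers, seed storage, reference genes and the genes listed as mutated. Lists on touch and wound response, shade avoidance and iron deficiency, 3 in all, were added after the values were seen. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), 165 tests in all, adjusted over the lists within each comparison. Of these 24 passed, and in each of the 24 the median, mean and test had the same sign. With a correlation estimated from the data 0 of the fixed lists passed, while fry, which asks whether the members of a list move one way and does not compare them with other genes, passed 21, and 73 in its version for changes in either direction. The estimated correlation rests on 3 or 4 residual degrees of freedom, so that version had little power. A list that fails it is not thereby shown to be unchanged. For fixed lists that passed camera, a fry value is printed below only where fry did not pass.

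Calls shared between comparisons were compared with the product of both counts over the genes tested, and between tables by Fisher's exact test, two-sided, adjusted over 12 tests. For comparisons that share Col-0 libraries, 100 draws of values without any difference (seed 1) gave the correlation, covariance and overlap that shared controls produce when no gene differs. They do not give the overlap that shared controls add among genes that do differ. Matched random lists (10000 draws, and 1000 for each of 20 other lists) and an exact permutation test over libraries were used for the touch genes.

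Alternatives tried were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 CPM, no trend, a fit on only the groups compared, a rescaling of libraries, a 2-fold minimum, a replicate block, a correlation estimated from the data and fry for the lists, and leaving out each library in turn. Leaving out together rrm1 replicate 1 and quadruple-mutant replicate 1, whose low values are shifted from whole numbers, leaving the 3 added lists out of the counts and shared calls, and splitting the 2 Col-0 libraries of a table between 2 mutants were added after the data were seen. Tests of single libraries as outliers, and of other splits of the samples for counts of called genes, do not apply to groups of 2. The loci mutated in rrm1 and pdp1/2/3 are not given in the sources used here. The 3 loci listed as PDP1, PDP2 and PDP3 were assigned without a source, and none was lower in pdp1/2/3, so those labels were not supported at their targets.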

Results

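RNA was sequenced from 11-day-old Arabidopsis thaliana seedlings as single-end reads of 50 nt, and values were deposited per gene and library in 2 tables. The first table held Col-0 (replicates 1 and 2), fve and suvh2/9. The second held another pair of Col-0 libraries (replicates 3 and 4), rrm1, pdp1/2/3 and the quadruple mutant that joins them. Each of the 7 groups had 2 libraries, 14 in all. Library totals were 21259805 to 21722950 adjusted counts in the first table and 18609045 to 19534578 in the second, so that 1 count corresponded to 0.0465 and 0.0520 adjusted counts per 1e+06 (CPM). A gene with no count in a library could still have had a level of up to 0.140 (first table) or 0.156 (second table) CPM from counting error alone. Between replicates of a group, Pearson's r across genes was 0.995 to 0.996 in the first table and 0.994 to 0.996 in the second. Libraries of different groups correlated at 0.991 to 0.994 and 0.977 to 0.992, and genes are not independent replicates in these values. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries. They assign each pair of Col-0 libraries to the mutants of its table, but do not say which groups were grown and harvested together. In the second table Col-0 is numbered 3 and 4 and the mutants 1 and 2, so every difference from Col-0 there also holds any difference between harvests. Levels are given in CPM, mean ± SD (n = 2), and differences as log2 differences of the level plus 1. This shrinks differences, most of all those of genes below about 1 CPM. Counts at a 2-fold minimum use the level plus 1, so some genes whose CPM differed 2-fold are not among them.

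FVE is a histone-binding WD-repeat protein of the autonomous flowering pathway, which keeps the floral repressor FLC low. SUVH2 and SUVH9 bind methylated DNA and are needed to bring RNA polymerase V to its targets in RNA-directed DNA methylation. The PWWP-domain PDP proteins have been described as partners of FVE. The comparisons ask which transcripts depend on FVE, on SUVH2 and SUVH9, and on the proteins altered in the second table, and which of these are shared.

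**Figure D1:**
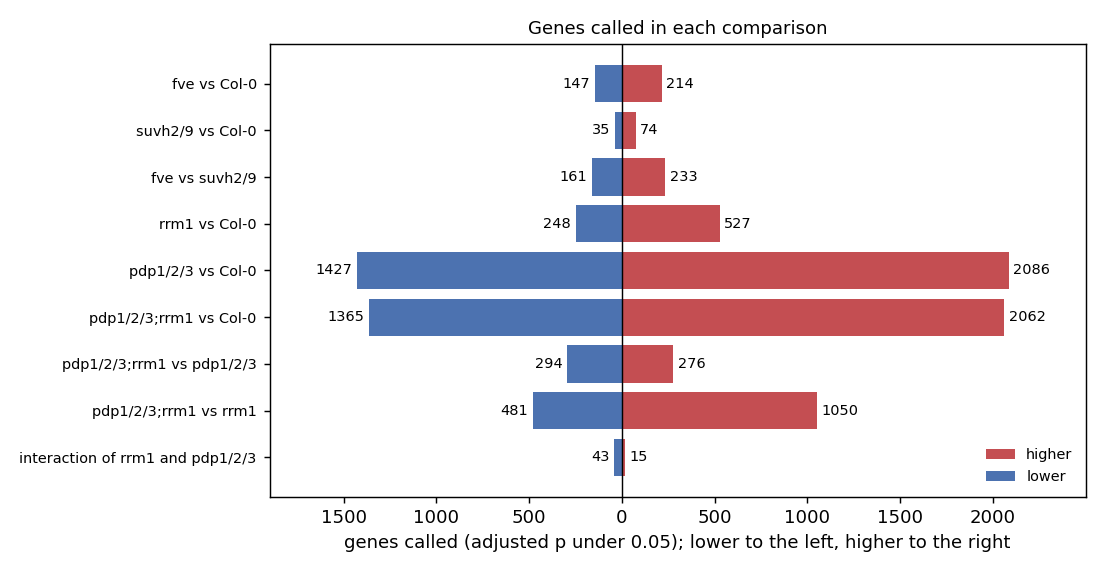
Number of genes called higher (right, red) and lower (left, blue) at an adjusted p below 0.05 in each of the 9 comparisons, 2 libraries per group. The bars are longest for pdp1/2/3 and the quadruple mutant against Col-0, with 3513 and 3427 genes.

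The fve mutant was compared with Col-0 to find the transcripts that depend on FVE. FLC and its relatives MAF4 and MAF5, repressors of flowering, rose, while SOC1, a promoter of flowering that FLC represses, fell. The FVE transcript itself fell. Several loci without a described function rose, and AT1G64795 fell to almost nothing. Of 19090 genes tested, limma called 361, 214 higher and 147 lower, and 72 of them differed at least 2-fold. With a mean of at least 5 CPM the calls were 92 higher and 103 lower, so which direction holds more genes depends on that filter.

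FVE (AT2G19520, chromosome 2, 8455756 to 8459642 in TAIR10.1) fell from 66.5 ± 0.990 in Col-0 to 15.3 ± 0.307 in fve, a log2 difference of -2.05 (SE 0.068, adjusted p = 4.75e-08). FLC (AT5G10140, chromosome 5, 3173382 to 3179448) rose from 0.371 ± 0.0716 to 11.2 ± 0.223, a log2 difference of 3.16 (SE 0.139, adjusted p = 6.02e-07). MAF5 (AT5G65080, chromosome 5, 25997504 to 26002619) rose from 0.347 ± 0.159 to 3.89 ± 0.342 (log2 1.86, adjusted p = 0.000212), and its neighbour MAF4 (AT5G65070, 25992193 to 25996202) from 0.787 ± 0.250 to 3.52 ± 0.472 (log2 1.34, adjusted p = 0.00127). Of the 6 genes of the FLC clade 3 rose and 3 were not called, with the same counts adjusted over the list alone, and the clade passed the camera test (adjusted p = 0.000136; adjusted p = 0.851 with an estimated correlation). SOC1 (AT2G45660, chromosome 2, 18807505 to 18811125) fell from 38.7 ± 4.88 to 17.0 ± 4.04 (log2 -1.16, adjusted p = 0.000902; 0.0679 when no filter on low values was applied). FT, the mobile flowering signal, was below the filter on low values, at 0.642 and 0.516 in the Col-0 libraries and 0 and 0.0925 in the fve libraries (log2 -0.59, adjusted p = 0.151 without a filter). Among loci without a described function, AT1G77960 rose from 3.92 ± 0.620 to 18.5 ± 1.47 (log2 1.99, adjusted p = 1e-05) and AT4G07995 from 4.1 ± 0.362 to 16.2 ± 0.286 (log2 1.75, adjusted p = 3.59e-06). AT5G35480 and AT1G29560 rose by 1.72 and 1.69 on the log2 scale (adjusted p = 1e-05 and 6.76e-05). AT1G64795 (chromosome 1, 24082579 to 24082848) fell from 8.92 ± 1.34 to 0.0696 ± 0.0985 (log2 -3.21, adjusted p = 7.95e-07), and BAM6, a beta-amylase gene, fell by 1.06 on the log2 scale (adjusted p = 0.00186; 0.0626 without a filter). ROS1, the DNA demethylase gene whose level follows RNA-directed DNA methylation, was at 46.3 ± 0.590 in fve and 60.4 ± 0.615 in Col-0 and did not pass (log2 -0.38, adjusted p = 0.0591), but passed without suvh2/9 replicate 1 (0.00398) or 2 (0.00441) and with only fve and Col-0 in the fit (0.00196). SDC, silenced by DNA methylation, was at 0.603 and 0.369 in the fve libraries and at 0 and 0.0468 in Col-0 (adjusted p = 0.155; 0.00921 with a pseudocount of 0.1). The imprinted gene FWA, also silenced by methylation, was at 0.371 and 0.277 in fve and at 0.0920 and 8.35e-05 in Col-0. Of 14 cold-regulated genes limma called 0, with 5 higher at an unadjusted p below 0.05 and 3 (COR15B, ERD10 and GOLS3) higher when adjusted over the list alone. That list passed camera at an adjusted p of 0.00104, not with an estimated correlation (adjusted p = 0.937), without Col-0 replicate 1 (0.134), with no filter (0.0527) or by fry (0.612). The number of genes called was 110 and 134 without Col-0 replicate 1 and 2, 100 and 101 without fve replicate 1 and 2, and 662 and 666 without suvh2/9 replicate 1 and 2.

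In suvh2/9, compared with Col-0 to find the transcripts that depend on SUVH2 and SUVH9, the demethylase gene ROS1 fell steeply and SDC, whose promoter repeats are silenced by DNA methylation, came on. Several non-coding and uncharacterised loci, some of them nearly silent in Col-0, rose steeply. The SUVH9 transcript was nearly lost. The flowering genes FLC and SOC1 were not called. Of 19090 genes, 109 were called, 74 higher and 35 lower, and 49 differed at least 2-fold.

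SUVH9 (AT4G13460, chromosome 4, 7823894 to 7827004) fell from 41.7 ± 1.48 to 1.03 ± 0.130 (log2 -4.39, SE 0.088, adjusted p = 8.13e-11). SUVH2 (AT2G33290, chromosome 2, 14108529 to 14112464) was at 7.31 ± 0.0469 against 9.46 ± 0.0467 and did not pass (log2 -0.33, adjusted p = 0.335). ROS1 (AT2G36490, chromosome 2, 15307907 to 15314807) fell from 60.4 ± 0.615 to 4.75 ± 0.737 (log2 -3.42, SE 0.089, adjusted p = 7.77e-10). SDC (AT2G17690, chromosome 2, 7682162 to 7684083) was at 0 and 0.0468 in the Col-0 libraries and rose to 7.70 and 6.17 in suvh2/9 (adjusted p = 1.53e-06). AT3G01345 (chromosome 3, 129138 to 130749, protein-coding) rose from 0.233 ± 0.201 to 132 ± 72.3 (log2 6.65, adjusted p = 7.22e-08). The non-coding RNA AT1G67105 (chromosome 1, 25057479 to 25058264) rose from 15.9 ± 0.843 to 338 ± 29.8 (log2 4.33, SE 0.072, adjusted p = 2e-11). AT2G01422, AT4G07995 and AT3G29639 rose by 4.35, 4.20 and 4.06 on the log2 scale (adjusted p = 6.87e-08, 2.41e-10 and 2.16e-08). CSLB03, a cellulose synthase-like gene, fell by 1.09 on the log2 scale (adjusted p = 8.16e-06), CYP702A5 fell by 1.33 (adjusted p = 0.000271; 0.0616 without a filter) and GRP5, a glycine-rich protein gene, fell by 2.06 (adjusted p = 0.000545; 0.111 without a filter). QQS, a starch regulator gene that differs in methylation between accessions, fell from 7.98 ± 3.78 to 1.43 ± 0.367 (log2 -1.82, adjusted p = 0.00236; 0.184 without a filter and 0.0745 without a mean-variance trend). Of the 3 tested genes silenced by DNA methylation, SDC rose, QQS fell and 1 was not called. FLC was at 0.682 ± 0.0344 (log2 0.30, adjusted p = 0.772) and SOC1 at 47.9 ± 4.21 (log2 0.30, adjusted p = 0.725). FT was at 0.563 and 0.236 and FWA at 0.188 in both suvh2/9 libraries. MORC6 rose by 0.47 on the log2 scale among 21 genes of the RNA-directed DNA methylation machinery, with an adjusted p of 0.0388, and lost its call without any 1 of the 6 libraries of the table (adjusted p = 0.0596 to 0.447), without a filter (0.212), without a trend (0.12) and with only the groups compared (0.0933). Photosynthesis genes and root markers passed camera as higher (adjusted p = 0.00702 and 0.00891; 0.588 each with an estimated correlation, 0.0888 and 0.0581 without a filter, 0.445 and 0.477 by fry), although limma called 0 of 20 and 0 of 16 (2 and 4 at an unadjusted p below 0.05). Both list tests were lost without Col-0 replicate 1 (0.372 each), photosynthesis also without suvh2/9 replicate 2 (0.127) and root markers without suvh2/9 replicate 1 (0.174). Without Col-0 replicate 1 or 2 the number of genes called was 53 or 51.

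The direct comparison of fve with suvh2/9 tested which of these changes differ between the mutants. FLC, MAF5 and MAF4 were higher in fve by 2.86, 1.91 and 1.22 on the log2 scale (adjusted p = 3.63e-07, 0.000139 and 0.00219), and SOC1 was lower (log2 -1.46, adjusted p = 0.000139). ROS1 was higher in fve than in suvh2/9 (46.3 against 4.75, log2 3.05, adjusted p = 3.95e-09) and SDC lower (log2 -2.41, adjusted p = 1.07e-05). AT3G01345, AT2G01422 and AT3G29639 were lower in fve (log2 -6.54, -4.69 and -3.63, adjusted p = 9.84e-08, 4.11e-08 and 5.48e-08), and AT1G77960 was higher (log2 2.01, adjusted p = 4.58e-06). The FLC clade passed camera (3 of 6 higher, adjusted p = 0.000177; adjusted p = 0.822 with an estimated correlation). In all, 394 genes were called, 233 higher and 161 lower in fve, and 98 or 118 without fve replicate 1 or 2.

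In both fve and suvh2/9, 37 genes were called in the same direction against Col-0, 27 higher and 10 lower, where independent calls would give 0.830 and 0.270, and 2 were called in opposite directions. AT4G07995 (chromosome 4, 4842688 to 4843814) and AT1G67105 were among the 27. Both mutants share the same Col-0 libraries, which alone gives a correlation of 0.499 between the log2 differences in 100 simulated draws, against 0.372 measured, and an average of 0.31 shared calls (at most 2). The covariance was 0.0132 against 0.00611 in the draws. No gene differed in the draws, so their shared calls do not measure what shared controls add among changed genes. Part of the excess may come from the shared controls. With the Col-0 libraries split, 1 for each mutant, which assumes that a lone library varies like the others, 17 or 13 genes were called the same way in the 2 possible orders (11 and 10 higher, against 0.187 and 0.158 for independent calls), with covariances of 0.0073 and 0.00647. The shared count rested on every library, being 16 and 18 without Col-0 replicate 1 and 2, 21 and 18 without fve replicate 1 and 2, and 58 without either suvh2/9 library.

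**Figure D2:**
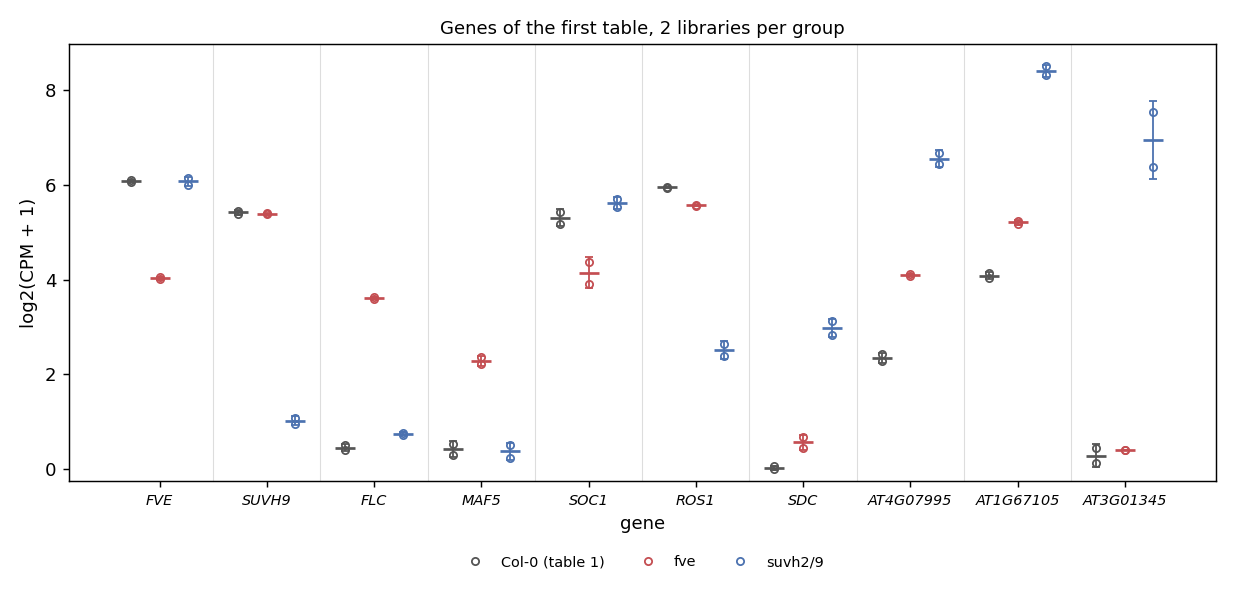
Level of 10 genes in Col-0, fve and suvh2/9 as log2(CPM + 1), with open circles for libraries, a short line for the mean and bars for the SD (n = 2). FLC and MAF5 are highest in fve, whereas in suvh2/9 ROS1 and SUVH9 are lowest and SDC, AT1G67105 and AT3G01345 highest. AT1G67105 is also higher in fve than in Col-0 (log2 1.12, adjusted p = 1.06e-05).

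In rrm1, compared with the Col-0 libraries of its own table, MAF4 and MAF5 rose without FLC. TEM1 and TEM2, repressors of FT outside the FLC clade, also rose. The seed storage gene CRA1 came on, while the pathogenesis-related genes PR1 and PR2 and the starch regulator QQS were lower than in Col-0. Genes that answer touch and wounding were higher too: in a list chosen after the values were seen, 10 of 13 were called higher (median log2 1.12). Of 19241 genes tested, 775 were called, 527 higher and 248 lower, and 138 differed at least 2-fold in the level plus 1.

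MAF5 rose from 0.600 ± 0.0504 to 8.14 ± 1.5 (log2 2.50, SE 0.127, adjusted p = 4.1e-06) and MAF4 from 0.573 ± 0.0130 to 3.41 ± 0.188 (log2 1.49, adjusted p = 0.00015), while FLC was at 0.480 ± 0.0994 against 0.365 ± 0.0654 (log2 0.12, adjusted p = 0.793). The FLC clade passed camera (adjusted p = 0.00547; adjusted p = 0.417 with an estimated correlation). SOC1 fell from 63.2 ± 1.09 to 44.4 ± 2.78 (log2 -0.50, adjusted p = 0.0084), a call lost without Col-0 replicate 3 (0.0877) or 4 (0.0644) or rrm1 replicate 1 (0.0834), and without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.072). In the Col-0 libraries of the first table SOC1 was at 35.3 and 42.2 CPM, below its mean level in rrm1. TEM1 (AT1G25560, chromosome 1, 8981556 to 8983314) rose from 17.9 ± 3.72 to 63.9 ± 16.7 (log2 1.77, adjusted p = 0.00015) and TEM2 (AT1G68840, chromosome 1, 25880155 to 25882222) from 40.2 ± 13.6 to 125 ± 25.3 (log2 1.64, adjusted p = 0.00052). CRA1 (AT5G44120, chromosome 5, 17756238 to 17758336) rose from 0.287 ± 0.0303 to 17.0 ± 8.35 (log2 3.72, SE 0.271, adjusted p = 3.05e-05). The floral organ genes PI and SEP3, targets of Polycomb repression, rose by 1.70 and 1.31 on the log2 scale (adjusted p = 0.00024 and 0.00229). DIC2, AT1G07135 and CAF1a, which was in the touch list, rose by 2.52, 2.22 and 2.16 (adjusted p = 0.00417, 0.00295 and 0.00128), the first not without a filter (0.0605). QQS (AT3G30720, chromosome 3, 12349047 to 12349933) fell from 16.5 ± 0.145 to 1.74 ± 0.727 (log2 -2.70, SE 0.17, adjusted p = 1.57e-05). PR2 (AT3G57260, chromosome 3, 21188397 to 21189967) fell from 19.6 ± 2.54 to 2.02 ± 0.830 (log2 -2.79, adjusted p = 0.0015), AT1G04280 from 40.6 ± 1.23 to 8.60 ± 0.237 (log2 -2.12, adjusted p = 5.39e-06), and PCC1 and LURP1, both tied to pathogen response, by 2.03 and 2.48 on the log2 scale (adjusted p = 3.05e-05 and 0.00457, the second 0.0616 without a filter). PR1, the marker of salicylic acid response, was at 8.00 ± 7.01 in Col-0 and 0.102 ± 0.0745 in rrm1 (log2 -2.77, adjusted p = 0.00577; 0.0632 without a filter and 0.0561 without rrm1 replicate 1 and quadruple-mutant replicate 1 together). In the Col-0 libraries of the first table PR1 was at 0.138 and 0.0939 and PR2 at 2.39 and 1.03. A high level in the Col-0 pair of the second table therefore cannot be told apart from a fall in the mutants. Of 13 salicylic acid and immune genes 3 fell, or 5 fell and 1 rose adjusted over the list alone, with camera at an adjusted p of 0.000892 (adjusted p = 0.263 with an estimated correlation). Of 16 cold-regulated genes 3 rose, or 7 adjusted over the list alone, CBF2 and COR413-IM1 among them (log2 1.21 and 0.75, adjusted p = 0.00315 and 0.00316), and the list passed camera (adjusted p = 0.000581; 0.562 with an estimated correlation and 0.114 by fry). Root markers passed camera as higher (1 of 16 called, 5 adjusted over the list alone, adjusted p = 0.0024; 0.569 with an estimated correlation and 0.114 by fry). Photosynthesis genes passed as lower (adjusted p = 0.00997; 0.575 with an estimated correlation, 0.0653 without a filter and 0.159 by fry), with 0 of 20 called by limma and 1 at an unadjusted p below 0.05, and lost the call without Col-0 replicate 4 (0.134) or rrm1 replicate 1 (0.0632), and without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.112). ROS1 was at 55.5 ± 0.304 against 48.2 ± 1.3 (adjusted p = 0.197). The number of genes called was 204 and 236 without Col-0 replicate 3 and 4, 313 and 334 without rrm1 replicate 1 and 2, and 1234 and 1222 without pdp1/2/3 replicate 1 and 2.

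In pdp1/2/3, all 3 of FLC, MAF4 and MAF5 rose against Col-0, SOC1 and SPL9, promoters of flowering, fell, and TEM1 and TEM2 rose. ROS1 rose, opposite in direction to its fall in suvh2/9. Among called genes with a mean of at least 5 CPM and no overlap between libraries, TCH4, BT2 and HB4 rose most. TCH4 is a touch-induced cell-wall gene, BT2 a nutrient-response gene and HB4 a shade-induced gene. Of the 13 touch and wound genes of the list chosen after the values were seen, 12 were called higher (median log2 1.85; camera with an estimated correlation, adjusted p = 0.104). The groups of Col-0 and pdp1/2/3 differed in 3513 of 19241 genes, 2086 higher and 1427 lower, and 451 differed at least 2-fold.

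FLC rose from 0.365 ± 0.0654 to 4.11 ± 1.59 (log2 1.87, SE 0.19, adjusted p = 4.32e-05), MAF5 from 0.600 ± 0.0504 to 7.82 ± 0.0111 (log2 2.46, adjusted p = 1.24e-06) and MAF4 from 0.573 ± 0.0130 to 1.98 ± 0.237 (log2 0.92, adjusted p = 0.000487). The clade did not pass camera (3 of 6 higher, adjusted p = 0.0549). SOC1 fell to 35.5 ± 3.60 (log2 -0.82, adjusted p = 5.68e-05) and SPL9 to 6.51 ± 0.641 from 13.1 ± 0.554 (log2 -0.91, adjusted p = 0.000228). Outside the FLC clade 2 of 7 repressors rose, TEM1 and TEM2 (log2 1.93 and 2.02, adjusted p = 1.13e-05 and 1.89e-05), and 2 fell, SNZ by 0.72 and TOE1 by 0.39 on the log2 scale (adjusted p = 0.000722 and 0.00758). ROS1 rose from 48.2 ± 1.3 to 81.9 ± 5.42 (log2 0.75, SE 0.08, adjusted p = 5.64e-05), and among the genes of methylation maintenance and demethylation 2 of 15 rose. TCH4 (AT5G57560, chromosome 5, 23307006 to 23308680) rose from 16.9 ± 2.44 to 458 ± 46.5 (log2 4.68, SE 0.52, adjusted p = 7.76e-05), BT2 (AT3G48360) from 9.78 ± 0.699 to 185 ± 0.361 (log2 4.11, adjusted p = 2.37e-06) and HB4 from 0.857 ± 0.460 to 28.5 ± 4.12 (log2 4.0, adjusted p = 1.58e-05). AT3G19680 and EXO, a brassinosteroid-induced growth gene, rose by 3.51 and 3.38 on the log2 scale (adjusted p = 3.18e-05 and 0.000136). AT3G09670, a PWWP-domain gene (chromosome 3, 2966201 to 2969058), fell from 14.0 ± 0.864 to 0.964 ± 0.176 (log2 -2.94, SE 0.139, adjusted p = 8.9e-07) and QQS to 1.2 ± 0.0640 (log2 -3.00, adjusted p = 2.14e-06). AT2G15020 fell by 2.14, PR2 by 2.15, PR1 by 2.1 and LURP1 by 2.05 on the log2 scale (adjusted p = 2.92e-05, 0.00136, 0.00612 and 0.00268). For PR1, PR2 and LURP1 the limit given above for the Col-0 levels holds here too. Of 13 salicylic acid and immune genes 3 fell, without a camera call (adjusted p = 0.175). Cold-regulated genes went both ways, 3 higher and 3 lower of 16, with ERD10 up by 0.45 and CBF3 down (log2 -1.51; adjusted p = 0.00209 and 0.000472). In the circadian clock list 2 of 16 rose and 1 fell: LUX was higher by 0.64 (adjusted p = 0.0012), TOC1 by 0.41 (adjusted p = 0.00818; 0.108 without Col-0 replicate 3), and PRR9 lower (log2 -1.05, adjusted p = 0.000197). Among the reference genes UBQ10 fell by 0.35 on the log2 scale, 1 of 7, with an adjusted p of 0.00769 that became 0.066 and 0.0553 without Col-0 replicate 3 and 4. The number of genes called was 1826 and 1908 without Col-0 replicate 3 and 4 and 2259 without pdp1/2/3 replicate 2.

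The quadruple mutant, against Col-0, had the highest mean levels of FLC, MAF4 and MAF5 among the 4 groups of the second table and the lowest of SOC1. CRA1 and PI rose as in rrm1, and ROS1, TEM1, TEM2, TCH4, BT2 and HB4 as in pdp1/2/3. QQS, PR1 and PR2 were lower than in Col-0, as in each of them, with the limit given above for the Col-0 levels of PR1 and PR2. That limit also holds for PCC1, LURP1 and the salicylic acid and immune list. All 13 touch and wound genes were called higher (median log2 1.74). Calls numbered 3427 of 19241 genes, 2062 higher and 1365 lower, and 424 differed at least 2-fold in the level plus 1.

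FLC reached 8.84 ± 0.0335 (log2 2.85, adjusted p = 3.49e-06), MAF5 18.6 ± 0.609 (log2 3.61, SE 0.127, adjusted p = 5.83e-08) and MAF4 7.23 ± 0.0983 (log2 2.39, adjusted p = 2.01e-06). The clade passed camera (adjusted p = 0.000129; adjusted p = 0.301 with an estimated correlation). SOC1 fell to 24.7 ± 1.73 (log2 -1.32, SE 0.087, adjusted p = 3.08e-06) and SPL9 by 0.93 on the log2 scale (adjusted p = 0.000232). FT was listed at 0 in both quadruple-mutant libraries and was at 0.154 and 0.264 in Col-0, 0.2 and 0.154 in rrm1 and 0.157 and 0.104 in pdp1/2/3, at most 5.1 adjusted counts and below the filter (quadruple mutant against Col-0 without a filter, log2 -0.27, adjusted p = 0.027). TEM1 and TEM2 were at 75.0 ± 9.29 and 160 ± 16.9 (log2 2.02 and 2.00, adjusted p = 8.46e-06 and 2.24e-05). ROS1 was at 74.6 ± 7.51 (log2 0.62, adjusted p = 0.000274). BT2, HB4 and DIC2 rose by 3.65, 3.60 and 3.57 on the log2 scale (adjusted p = 3.76e-06, 3.66e-05 and 7.61e-05), and TCH4 to 99.8 and 431 in the replicates (log2 3.55, adjusted p = 0.00067). CRA1 rose to 13.7 ± 4.44 (log2 3.48, adjusted p = 7.44e-06) and PI to 4.91 ± 0.233 (log2 1.86, adjusted p = 1.63e-05). QQS fell to 1.21 ± 0.127 (log2 -2.99, adjusted p = 2.01e-06), PCC1 by 2.45, PR2 by 2.43, PR1 by 2.39 and LURP1 by 2.19 on the log2 scale (adjusted p = 2.01e-06, 0.000706, 0.00308 and 0.00206). AT3G09670 fell to 1.98 ± 0.442 (log2 -2.34, adjusted p = 2.01e-06). Of 16 cold-regulated genes 7 rose and 1 fell, or 11 and 2 adjusted over the list alone, with CBF1 up by 1.54 and COR413-IM1 by 0.80 (adjusted p = 0.00024 and 0.00036), and the list passed camera (adjusted p = 0.00646; 0.538 with an estimated correlation, 0.187 with a mean of at least 5 CPM, 0.141 without quadruple-mutant replicate 1 and 0.0908 without rrm1 replicate 1 and quadruple-mutant replicate 1 together). Jasmonate genes rose in 4 of 8 members, VSP2 and JAZ1 by 0.69 and 1.02 (adjusted p = 0.00141 and 0.0018), with camera at 0.00748 (0.538 with an estimated correlation, 0.122 without a filter and 0.103 by fry). Of 13 salicylic acid and immune genes 4 fell, with camera at 0.0374 (0.443 with an estimated correlation), a call also lost with a pseudocount of 0.1 (0.0503), with a mean of at least 5 CPM (0.557), with only the groups compared (0.0763), without pdp1/2/3 replicate 1 or 2 (0.0513 and 0.0516) or quadruple-mutant replicate 1 (0.093), and without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.0908). In the clock list 4 of 16 rose, including LUX and TOC1 (log2 0.65 and 0.51, adjusted p = 0.00129 and 0.00248), and 3 fell, including PRR9 (log2 -0.75, adjusted p = 0.00236). The number of genes called was 1542 and 1841 without Col-0 replicate 3 and 4 and 1703 without quadruple-mutant replicate 2.

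The quadruple mutant was next set against pdp1/2/3, which gives the effect of rrm1 in the pdp1/2/3 background. MAF4 and MAF5 rose further (log2 1.47 and 1.15, adjusted p = 0.00019 and 7e-04) and SOC1 fell further (log2 -0.51, adjusted p = 0.0106; 0.0531 without a filter and 0.0587 without a trend). FLC was higher by 0.98 (adjusted p = 0.0187), a call lost without pdp1/2/3 replicate 1 (0.0829) or quadruple-mutant replicate 1 (0.115) or 2 (0.0758), without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.15), with a pseudocount of 0.1 (0.0569), without a filter (0.086) and without a trend (0.0513). CRA1 rose by 3.61, PI by 1.77, the myrosinase-binding gene MBP1 by 1.89, VSP2 by 1.00 and MYB51, a regulator of glucosinolates, by 1.40 on the log2 scale (adjusted p = 6.04e-05, 0.000207, 0.000579, 0.000829 and 6.04e-05). AT1G04280 (chromosome 1, 1143436 to 1147091) fell from 43.0 ± 8.98 to 9.21 ± 0.196 (log2 -2.09, adjusted p = 1.22e-05) and AT1G65370 by 1.53 (adjusted p = 0.000161). Cold-regulated genes rose in 5 of 16 members, or 9 adjusted over the list alone, with camera at an adjusted p of 8.84e-08 (0.332 with an estimated correlation and 0.192 by fry). The FLC clade passed camera (3 of 6, or 4 adjusted over the list alone, 7.44e-06; 0.219 with an estimated correlation), as did jasmonate genes (1 of 8, or 4, 0.0123; 0.712 with an estimated correlation, 0.156 without a filter, 0.323 by fry and 0.573 without pdp1/2/3 replicate 2). ROS1 did not differ detectably (log2 -0.14, adjusted p = 0.445). Of 19241 genes 570 were called, 276 higher and 294 lower, and 376 without pdp1/2/3 replicate 2 and 182 without quadruple-mutant replicate 1. Which direction held more genes was not stable, with 91 higher and 82 lower without a filter and 120 and 93 without a trend.

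Against rrm1, the quadruple mutant gives the effect of pdp1/2/3 in the rrm1 background. FLC rose by 2.73, MAF5 by 1.11 and MAF4 by 0.90 on the log2 scale (adjusted p = 1.83e-05, 0.000317 and 0.00166), and SOC1 fell from 44.4 to 24.7 (log2 -0.82, adjusted p = 0.00019). LOX4, a lipoxygenase gene of jasmonate synthesis, HB4 and BT2 rose by 2.82, 2.70 and 2.60 (adjusted p = 0.00019, 0.000748 and 0.000117), and 7 of 13 touch and wound genes were higher and 1 lower. AT3G09670 fell from 12.5 to 1.98 (log2 -2.18, adjusted p = 1.83e-05), MRN1 and PIP5K5 by 1.25 and 1.16 on the log2 scale (adjusted p = 0.00115 and 0.000277). ROS1 rose by 0.42 (adjusted p = 0.00783; 0.0726 without rrm1 replicate 1 and 0.168 without rrm1 replicate 1 and quadruple-mutant replicate 1 together). The FLC clade passed camera (adjusted p = 0.000414; 0.365 with an estimated correlation), and root markers passed as lower (3 of 16, or 4 adjusted over the list alone, 0.00213; 0.619 with an estimated correlation and 0.113 by fry). Jasmonate genes (higher) and cell division genes (lower) passed at 0.0484 each (0.619 each with an estimated correlation, 0.298 and 0.153 by fry, 0.137 and 0.0871 with a mean of at least 5 CPM, 0.466 and 0.579 without rrm1 replicate 1 and quadruple-mutant replicate 1 together), and jasmonate at 0.226 without a filter. Both were lost without rrm1 replicate 1 (0.103 and 0.199) or quadruple-mutant replicate 1 (0.325 and 0.397), and jasmonate also without rrm1 replicate 2 (0.0785). Of 19241 genes 1531 were called, 1050 higher and 481 lower, and 434, 1016 and 651 without rrm1 replicate 1, rrm1 replicate 2 and quadruple-mutant replicate 2.

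Whether the effect of rrm1 differed between the wild-type and the pdp1/2/3 background was tested as an interaction, which called 58 of 19241 genes, 15 with a positive and 43 with a negative term. QQS fell by 2.70 on the log2 scale with rrm1 alone and not further in pdp1/2/3 (interaction 2.71, SE 0.24, adjusted p = 0.00215, and 0.0593 without a filter), having already fallen there. Its falls in rrm1 and in pdp1/2/3 together exceed its whole Col-0 level on the log2 scale used. A level cannot go below that of a gene without reads, so a positive term for QQS was forced in part. It does not show how the genotypes combine. TEM1 and TEM2 rose with rrm1 in the wild-type background and not in pdp1/2/3, where both were already high (interaction -1.68 and -1.67, adjusted p = 0.018 and 0.0264), and MAF5 rose less there (interaction -1.35, adjusted p = 0.018). The calls of TEM1, TEM2 and MAF5 were lost without Col-0 replicate 3 (0.0786 each), and that of TEM2 also without pdp1/2/3 replicate 2 (0.0699), rrm1 replicate 2 (0.0774) or quadruple-mutant replicate 1 (0.0802). All 3 were also lost without a filter (TEM1, TEM2 and MAF5 at 0.205, 0.236 and 0.174) and without a trend (0.148, 0.16 and 0.0764), and MAF5 without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.0742). Photosynthesis and salicylic acid genes passed camera with positive terms (adjusted p = 0.0099 and 0.0183; 0.885 and 0.557 with an estimated correlation, 0.119 and 0.0778 without a filter), the first not without Col-0 replicate 4 (0.101) and neither without quadruple-mutant replicate 2 (0.0564 and 0.059). Photosynthesis was also lost by fry (0.451) and without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.201), and salicylic acid genes with a mean of at least 5 CPM (0.0828). The number of genes called was 5 and 29 without Col-0 replicate 3 and 4, 344 and 27 without pdp1/2/3 replicate 1 and 2, 88 and 9 without rrm1 replicate 1 and 2, and 34 and 281 without quadruple-mutant replicate 1 and 2.

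**Figure D3:**
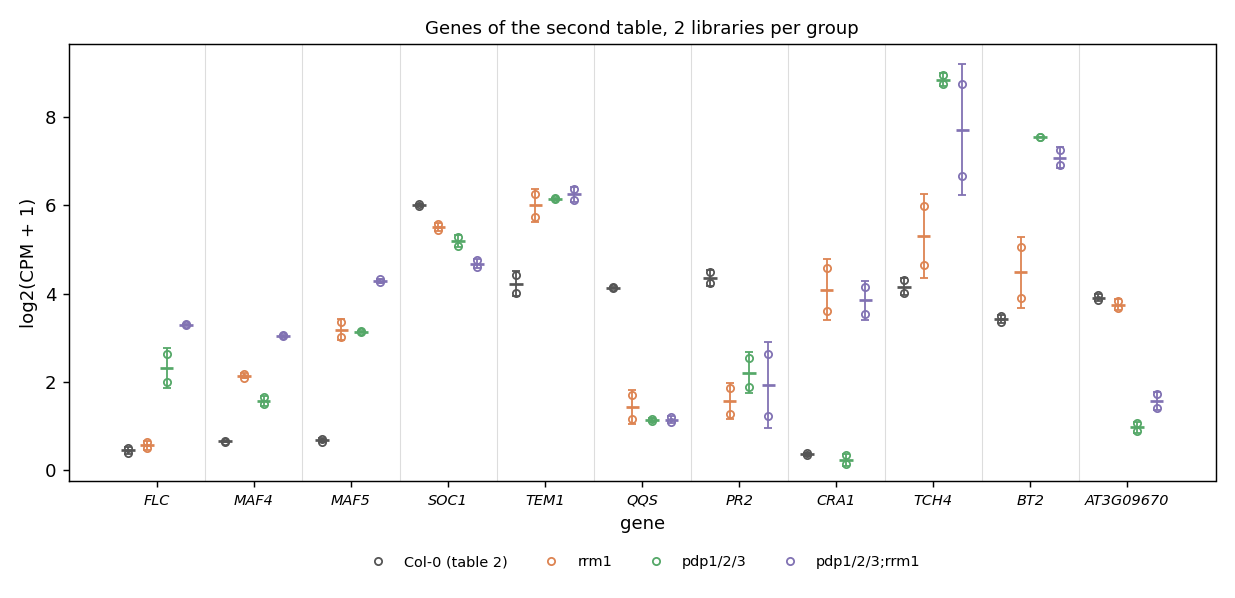
Level of 11 genes in Col-0, rrm1, pdp1/2/3 and the quadruple mutant as log2(CPM + 1), with open circles for libraries, a short line for the mean and bars for the SD (n = 2). FLC is high in both genotypes with pdp1/2/3, CRA1 in both with rrm1, and QQS and PR2 are low in all 3 mutants.

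Within the second table, 2164 genes were called the same way in pdp1/2/3 and the quadruple mutant (1397 higher, 767 lower, 224 and 101 for independent calls), 570 in rrm1 and the quadruple mutant (379 and 191, against 56.5 and 17.59) and 320 in rrm1 and pdp1/2/3 (211 and 109, against 57.1 and 18.4, with 29 in opposite directions). QQS, PR2, MAF4, MAF5, TEM1 and TEM2 belonged to all 3 sets. The log2 differences correlated across genes at 0.822, 0.675 and 0.462, where shared Col-0 libraries alone gave 0.502, 0.501 and 0.5 in simulated draws. Covariances were 0.104, 0.0576 and 0.0402 against 0.00734, 0.00732 and 0.00731, and the draws gave at most 2 shared calls. As no gene differed in the draws, these shared calls do not measure what shared controls add among changed genes. Part of the excess may come from shared controls. With 1 Col-0 library for each mutant, in the 2 possible orders, the 3 sets held 935 and 1014, 181 and 136, and 105 and 57 genes, with covariances of 0.0973 and 0.0969, 0.0534 and 0.048, and 0.0359 and 0.0308. Without Col-0 replicate 3 the 3 sets held 1007, 157 and 74 genes, and without Col-0 replicate 4 they held 1181, 209 and 116. The 2164 genes became 1253 without quadruple-mutant replicate 2. The 570 became 869 and 863 without pdp1/2/3 replicate 1 and 2, and 288 and 253 without rrm1 replicate 1 and 2. The 320 became 555 without pdp1/2/3 replicate 1, and 188 and 132 without rrm1 replicate 1 and 2.

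The fve calls were compared with those of the second table, which has its own Col-0 libraries, over 18810 genes tested in both. Fisher's exact test counts genes as independent although related genes vary together, so its p-values do not measure the spread between libraries. The share over all genes was not matched for expression level. Of the genes higher in fve, 52.0% were also higher in the quadruple mutant against 10.4% of all genes (Fisher's exact test, two-sided, adjusted p = 7.69e-48), and of those lower in fve 44.9% were also lower against 7.16% (adjusted p = 6.54e-36). That set of 169 genes, 103 higher and 66 lower (20.6 and 10.5 for independent calls), included FLC, MAF4, MAF5 and SOC1. With pdp1/2/3 the shares were 37.9% and 40.8% (135 genes, adjusted p = 1.63e-23 and 5.76e-29), and with rrm1 17.2% and 6.12% (43 genes, adjusted p = 6.17e-18 and 0.000129). Called in opposite directions were 15, 15 and 8 genes of fve with the quadruple mutant, pdp1/2/3 and rrm1. The suvh2/9 calls shared 20 genes with the quadruple mutant, 16 with pdp1/2/3 and 16 with rrm1, and 12, 9 and 3 were called in opposite directions. Genes lower in suvh2/9 were more often lower in the quadruple mutant (28.6%, adjusted p = 0.000159), pdp1/2/3 (22.9% against 7.49% of all genes, adjusted p = 0.0044) and rrm1 (14.3% against 1.23%, adjusted p = 0.00011), and genes higher in suvh2/9 more often higher in rrm1 (19.6% against 2.64%, adjusted p = 3.92e-07), but not detectably so in the quadruple mutant or in pdp1/2/3 (17.9% and 14.3%, adjusted p = 0.0848 and 0.383). QQS was lower in suvh2/9 and in all 3 mutants of the second table, where ROS1 did not fall. The 169 shared genes became 65 and 79 without Col-0 replicate 1 and 2, 59 and 61 without fve replicate 1 and 2, 265 without either suvh2/9 library and 111 without Col-0 replicate 3. The 135 genes became 45 and 59, 42 and 42, and 214 and 216 without replicate 1 and 2 of Col-0, fve and suvh2/9 in turn, and the 43 became 18 and 20, 14 and 13, and 69 and 69, as well as 25 and 21 without Col-0 replicate 3 and 4, and 24 and 27 without rrm1 replicate 1 and 2. For suvh2/9 the 20 genes became 6 without Col-0 replicate 1 or 2, 12 and 11 without Col-0 replicate 3 and 4, and 7 without quadruple-mutant replicate 2. Its 16 with pdp1/2/3 became 10 without Col-0 replicate 2, and 8 and 7 without Col-0 replicate 3 and 4. Its 16 with rrm1 became 7 without Col-0 replicate 1 or 2, 7 and 8 without Col-0 replicate 3 and 4, 6 and 9 without rrm1 replicate 1 and 2, and 31 without suvh2/9 replicate 2.

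**Figure D4:**
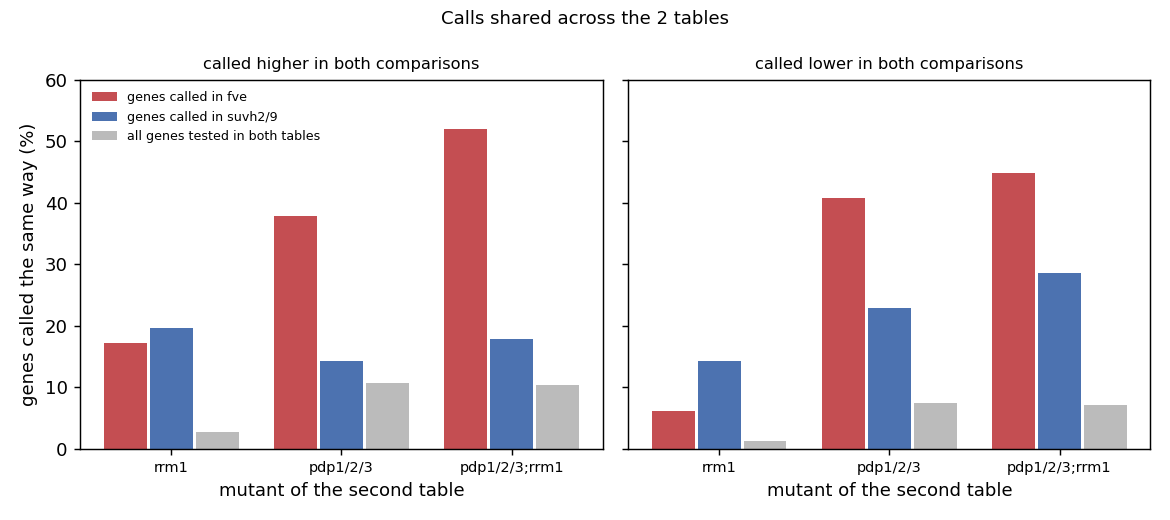
Percent of the genes called in fve, of those called in suvh2/9 and of all 18810 genes tested in both tables that were called the same way in rrm1, pdp1/2/3 and the quadruple mutant, for higher (left) and lower (right) genes. In pdp1/2/3 and the quadruple mutant the share is highest for genes called in fve (52.0% and 44.9% in the latter), and in rrm1 for genes called in suvh2/9 (19.6% and 14.3%).

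In the remaining listed groups, limma called 0 of 9 autonomous pathway genes, a list without FVE, and 0 of 8 subunits and partners of Polycomb Repressive Complex 2 in each of the 5 comparisons with Col-0, where at most 1 member went each way at an unadjusted p below 0.05. The RNA-directed DNA methylation machinery (21 genes) had 0 calls in fve and pdp1/2/3 (2 higher and 1 lower, and 2 and 2, at an unadjusted p below 0.05) and 1 each in suvh2/9, rrm1 and the quadruple mutant. In rrm1 this was MORC1, whose limma call was lost without a filter (adjusted p = 0.0777) and without a trend (0.0741). Methylation maintenance and demethylation genes had 0 calls in fve (1 and 1 unadjusted, 1 lower adjusted over the list alone) and rrm1 (2 higher unadjusted), and 1 in the quadruple mutant, ROS1. Of 7 heat shock genes, 1 rose in rrm1, 1 rose and 2 fell in the quadruple mutant, and 0 were called in fve (2 unadjusted), suvh2/9 (0 unadjusted) and pdp1/2/3 (1 unadjusted). The limma call in rrm1, that of HSP18.2, was lost without a filter (adjusted p = 0.0777) and when any single Col-0 or rrm1 library was left out. Anthocyanin and flavonoid genes rose in 2 of 10 members in rrm1, 2 in the quadruple mutant and 3 in pdp1/2/3, where 2 fell, and 0 were called in fve (2 unadjusted) and suvh2/9 (0 unadjusted). Those in rrm1, CHI and LDOX, lost their limma calls without a filter (adjusted p = 0.0834 and 0.147) and without a trend (0.0633 and 0.0943). Jasmonate genes rose in 1 of 8 members in rrm1 and 2 in pdp1/2/3. The limma call in rrm1, that of VSP1, was lost without a filter (adjusted p = 0.15), with a mean of at least 5 CPM (0.0509) and without a trend (0.11). Cell division genes had 1 call in pdp1/2/3 (higher) and 1 in the quadruple mutant (lower) out of 11, and floral promoters 1 lower in fve and rrm1 and 2 lower in pdp1/2/3 and the quadruple mutant out of 7. Among developmental Polycomb targets 1 of 5 fell in fve, SEP3, at an adjusted p of 0.0353 that did not hold without Col-0 replicate 1 (0.302) or 2 (0.114) or fve replicate 1 (0.1) or 2 (0.303), without a filter (0.17) or without a trend (0.0989), and in pdp1/2/3 0 of 4 were called (0 unadjusted). Of the seed storage genes 2 were tested in the second table, of which CRA1 was called in rrm1 and the quadruple mutant, and none in the first table. Of 7 reference genes 0 were called in fve, suvh2/9 and rrm1 (0 unadjusted in each), and UBQ10 was lower in the quadruple mutant as well as in pdp1/2/3 (log2 -0.31, adjusted p = 0.0139), a call lost without Col-0 replicate 3 (0.0988) or 4 (0.0797) or quadruple-mutant replicate 2 (0.125), or without a filter (0.0578).

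The genes that the labels name as mutated gave a partial check of the labels. FVE fell in fve and SUVH9 in suvh2/9, where SUVH2, the other gene named, did not pass (adjusted p = 0.335). In the other genotypes neither FVE nor SUVH2 was called. SUVH9 was lower by 0.29, 0.24 and 0.23 on the log2 scale in rrm1, pdp1/2/3 and the quadruple mutant (log2 -0.29, -0.24 and -0.23, adjusted p = 0.0389, 0.0331 and 0.0387), calls that were lost without either Col-0 library of that table (0.237 and 0.206, 0.181 and 0.136, and 0.2 and 0.147), without rrm1 replicate 1 or 2 in rrm1 (0.175 and 0.159) and the quadruple mutant (0.056 and 0.0557), without pdp1/2/3 replicate 1 or 2 in pdp1/2/3 (0.121 and 0.0613), without quadruple-mutant replicate 2 in that mutant (0.208), or without a trend (0.105, 0.0756 and 0.0826), and in rrm1 also without a filter (0.069); without rrm1 replicate 1 and quadruple-mutant replicate 1 together those of rrm1 and the quadruple mutant were at 0.146 and 0.0561. The sources used here do not give the loci mutated in pdp1/2/3 and rrm1. The loci AT5G27650, AT1G51745 and AT3G21295 of the PWWP family were taken beforehand as PDP1, PDP2 and PDP3, an assignment that these sources do not give. None was lower in pdp1/2/3 (log2 0.20, 0.42 and 0), so they did not support the label. AT5G27650 rose in fve from 31.9 ± 1.5 to 49.5 ± 1.19 (log2 0.62, adjusted p = 0.00124). In the quadruple mutant it was higher than in Col-0 by 0.26 (adjusted p = 0.0256) and than in rrm1 by 0.26 (adjusted p = 0.0409). The first call was lost without Col-0 replicate 3 (0.106) or 4 (0.16), quadruple-mutant replicate 1 (0.0659) or 2 (0.104), without a trend (0.0638) and without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.0668), and the second without any 1 of the 6 libraries of Col-0, rrm1 and the quadruple mutant (0.0503 to 0.313), without a filter (0.0603), without a trend (0.0981), with only the groups compared (0.0819) and without rrm1 replicate 1 and quadruple-mutant replicate 1 together (0.351). AT1G51745 was higher in pdp1/2/3 (log2 0.42, adjusted p = 0.00966; 0.114 without Col-0 replicate 3 and 0.0531 without pdp1/2/3 replicate 2), and AT3G21295 was not called in any comparison. Of all 16 annotated genes of the Tudor, PWWP and MBT family, each of them tested, 1 was lower in pdp1/2/3 (AT3G09670) and 2 in the quadruple mutant, AT3G09670 and AT5G40340, which fell from 77.9 ± 1.49 to 52.6 ± 3.38 (log2 -0.56, adjusted p = 0.000999).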

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

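Which genes to describe here was fixed beforehand except for MYB51 and CAF1a, whose left-out libraries were examined after the results were seen, when leaving out 2 libraries together was also chosen. In 58 genes the effect of rrm1 in the wild-type background differed from its effect in pdp1/2/3 by the interaction test of limma, 43 of them with a negative term, that is a smaller rise or a stronger fall in pdp1/2/3. QQS, the starch regulator gene, had the smallest p of the named ones: its level fell by 2.70 on the log2 scale with rrm1 alone and differed by 0.01 in pdp1/2/3, an interaction of 2.71 (adjusted p = 0.00215) that held without each single library and reached 0.0593 without a filter on low values. A positive term for QQS was forced in part, because its 2 single falls together exceed its whole Col-0 level on the log2 scale used. The QQS term therefore does not show how the genotypes combine. The floral repressors TEM1 and TEM2 rose by 1.77 and 1.64 with rrm1 in the wild type and by 0.09 and -0.02 in pdp1/2/3, interactions of -1.68 and -1.67 (adjusted p = 0.018 and 0.0264). MAF5 rose in both backgrounds, by 2.50 and 1.15, an interaction of -1.35 (adjusted p = 0.018). CAF1a, a touch-induced deadenylase gene, rose by 2.16 in the wild type and differed by -0.25 in pdp1/2/3, an interaction of -2.41 (adjusted p = 0.0264). MYB51, a regulator of glucosinolates, went the other way, with 0.45 and 1.40 and an interaction of 0.95 (adjusted p = 0.0264).

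Of these 6 genes TEM1, TEM2, MAF5, MYB51 and CAF1a lost their calls under other settings and without single libraries. Without a filter on low values they reached 0.205, 0.236, 0.174, 0.205 and 0.253, and without a mean-variance trend 0.148, 0.16, 0.0764, 0.148 and 0.16. Without rrm1 replicate 1 and quadruple-mutant replicate 1 together MAF5, MYB51 and CAF1a reached 0.0742, 0.148 and 0.0592. Without Col-0 replicate 3 all 5 reached 0.0786. The call of TEM2 was also lost without pdp1/2/3 replicate 2 (0.0699), rrm1 replicate 2 (0.0774) and quadruple-mutant replicate 1 (0.0802), that of CAF1a without rrm1 replicate 2 (0.0897) and quadruple-mutant replicate 1 (0.0919), and that of MYB51 without Col-0 replicate 4 (0.0859), rrm1 replicate 1 (0.0605) or 2 (0.0648) and quadruple-mutant replicate 1 (0.0766). The number of genes called was 5 and 29 without Col-0 replicate 3 and 4, 344 and 27 without pdp1/2/3 replicate 1 and 2, 88 and 9 without rrm1 replicate 1 and 2, and 34 and 281 without quadruple-mutant replicate 1 and 2. For QQS, TEM1 and TEM2 the level in pdp1/2/3 had already moved from Col-0 as far as in the quadruple mutant. Genotype effects that do not add on the log2 scale cannot be told apart here from a difference in harvest of the Col-0 pair. The touch and wound and the shade lists, chosen after the values were seen, also had negative terms (medians -1.18 and -0.955). Of their genes 8 of 13 and 10 of 11 were lower adjusted over the list alone, and 2 in each adjusted over all genes. No technical explanation was tested for the interaction genes as a group.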

How the results depend on the processing

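Leaving out together rrm1 replicate 1 and quadruple-mutant replicate 1, leaving out the 3 added lists, and splitting the Col-0 libraries were chosen after the results were seen; the other alternatives were not. No named gene or fixed list that was called changed direction under any alternative. The larger side of the higher and lower calls did change in 4 comparisons: in fve (214 and 147 as reported) to 92 and 103 with a mean of at least 5 CPM, in fve against suvh2/9 (233 and 161) to 55 and 63 without fve replicate 2, for the interaction (15 and 43) to 2 and 1 without a trend, and in the quadruple mutant against pdp1/2/3 (276 and 294) to 91 and 82 without a filter, 120 and 93 without a trend, 37 and 30 with a 2-fold minimum, 220 and 217 without Col-0 replicate 3, 220 and 219 without Col-0 replicate 4, 237 and 201 without pdp1/2/3 replicate 1 and 94 and 88 without quadruple-mutant replicate 1. Of 287 named gene and comparison results 244 were called, of which 157 kept their call whenever a single library was left out and 144 in all runs that tested them; over the other alternatives 222 calls were lost and 3 gained, and over left-out libraries 265 lost and 2 gained. Of 24 list calls 13 held without each single library and 0 in all runs. Counts stayed within 1.5 times of those reported with pseudocounts of 0.1 and 0.5, after rescaling the libraries and without the 3 added lists. Counts outside that range are given below; the block among the mutants of the second table and the ranges over left-out libraries are given whether or not they lay outside it. The cause was not tested unless stated.

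With no filter on low values, calls numbered 125 in fve, 59 in suvh2/9, 183 in fve against suvh2/9, 270 in rrm1, 173 in the quadruple mutant against pdp1/2/3, 843 against rrm1 and 2 for the interaction. Calls shared in direction were then 16 (fve and suvh2/9), 109 (rrm1 and pdp1/2/3) and 217 (rrm1 and the quadruple mutant), and with rrm1, pdp1/2/3 and the quadruple mutant in turn 8, 47 and 64 for fve and 2, 7 and 4 for suvh2/9. With a mean of at least 5 CPM, which tests fewer genes, calls numbered 195 in fve, 62 in suvh2/9, 213 between them and 33 for the interaction, shared calls 21 (fve and suvh2/9), 22, 81 and 99 for fve and 7, 10 and 12 for suvh2/9 in the same order, and 15 lists passed. Without a mean-variance trend, calls numbered 213 in fve, 63 in suvh2/9, 248 between them, 419 in rrm1, 213 in the quadruple mutant against pdp1/2/3, 957 against rrm1 and 3 for the interaction, and shared calls 18 (fve and suvh2/9), 154 and 315 for rrm1 with pdp1/2/3 and the quadruple mutant, 20, 78 and 103 for fve and 5, 8 and 3 for suvh2/9. With a fit on only the groups compared, which cannot give an interaction, calls numbered 650 in fve, 1752 in rrm1 and 377 in the quadruple mutant against pdp1/2/3, and shared calls 637 and 1121 for rrm1 with pdp1/2/3 and the quadruple mutant and 120, 210 and 295 for fve. The labels give replicate numbers no meaning across groups. Replicate differences correlated across genes at 0.144 and 0.197 for suvh2/9 with Col-0 and fve but at 0.006 for Col-0 with fve, and at -0.1 to -0.011 between mutants of the second table, so the numbers were not taken as pairs, although a part shared by the numbers of the first table is not excluded. With replicate number as a block in the first table, calls numbered 643 in fve, 178 in suvh2/9 and 698 between them, and shared calls 66 (fve and suvh2/9), 72, 219 and 268 for fve and 25, 26 and 36 for suvh2/9; among the mutants of the second table a block gave 431 and 1184 calls for the quadruple mutant against pdp1/2/3 and rrm1, and 436 and 1261 without it on the same libraries. A 2-fold minimum, which keeps a part of the calls, left 72 in fve, 49 in suvh2/9, 79 between them, 138 in rrm1, 451 in pdp1/2/3, 424 in the quadruple mutant, 67 and 163 for it against pdp1/2/3 and rrm1 and 35 for the interaction. It left shared calls of 15 (fve and suvh2/9), 63 and 94 for rrm1 with pdp1/2/3 and the quadruple mutant, 285 (pdp1/2/3 and the quadruple mutant), 6, 12 and 15 for fve and 5, 1 and 1 for suvh2/9. With a correlation estimated from the data 0 of the fixed lists passed, against 24 with the preset one. That estimate rests on few residual degrees of freedom, so failing it decides little about a list. With the Col-0 libraries split, 1 for each of 2 mutants, the 2 orders gave shared calls of 17 and 13 (fve and suvh2/9), 105 and 57 (rrm1 and pdp1/2/3), 181 and 136 (rrm1 and the quadruple mutant) and 935 and 1014 (pdp1/2/3 and the quadruple mutant). Without both libraries whose low values were shifted, which leaves single libraries of those groups, calls numbered 341 in rrm1, 166 and 618 in the quadruple mutant against pdp1/2/3 and rrm1, and shared calls 210 and 296 for rrm1 with pdp1/2/3 and the quadruple mutant, 23 for fve with rrm1, and 7 and 13 for suvh2/9 with rrm1 and the quadruple mutant.

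With single libraries left out in turn, where the lone library of a group is assumed to vary like the others, calls ranged from 100 to 666 in fve, 51 to 156 in suvh2/9, 98 to 452 between them, 204 to 1234 in rrm1, 1826 to 3571 in pdp1/2/3, 1542 to 3832 in the quadruple mutant, 182 to 508 and 434 to 1821 for it against pdp1/2/3 and rrm1, and 5 to 344 for the interaction, and 21 to 30 lists passed. Shared calls ranged from 16 to 58 (fve and suvh2/9), 74 to 555 (rrm1 and pdp1/2/3), 157 to 869 (rrm1 and the quadruple mutant) and 1007 to 2182 (pdp1/2/3 and the quadruple mutant). Across tables, with rrm1, pdp1/2/3 and the quadruple mutant in turn, they ranged from 13 to 69, 42 to 216 and 59 to 265 for fve, and from 6 to 31, 7 to 24 and 6 to 30 for suvh2/9. The counts thus rest on which libraries were included, while FVE, FLC, MAF4 and MAF5 in fve, SUVH9, ROS1 and SDC in suvh2/9, and MAF4, MAF5, TEM1, TEM2, QQS, CRA1 and PR2 in rrm1 and the quadruple mutant kept their calls in all runs that tested them; FLC, MAF4 and MAF5 without an fve library, and SDC without a suvh2/9 library, fell below the filter and were not tested. Depth limits FT (at most 13.8 adjusted counts in a library of the first table and 5.1 of the second), FWA (8 and 1) and, in the second table, SDC (3), which were below the filter; without it FT in the quadruple mutant (log2 -0.27, adjusted p = 0.027) and SDC in pdp1/2/3 (log2 0.21, adjusted p = 0.0154) were called against Col-0 on these counts. Tests on whole reads with edgeR or DESeq2 could not be run on adjusted counts.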

Other observations

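The lists, genes and tests given here were chosen after the values were seen. A short protein-coding locus, AT1G64795 (chromosome 1, 24082579 to 24082848), was lost in fve and in every mutant of the second table but kept in suvh2/9. Its level was 9.86 and 7.97 CPM in Col-0, 0.139 and 0 in fve and 8.35 and 6.87 in suvh2/9. In the second table it was 4.15 and 5.87 in Col-0 and 0.0523 and 0 in pdp1/2/3, and it was listed at 0 in rrm1 and the quadruple mutant (adjusted p = 3.05e-05, 5.04e-06 and 3.85e-06 for rrm1, pdp1/2/3 and the quadruple mutant). Whether the locus is deleted in these lines or not transcribed cannot be read from expression values.

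Shade avoidance genes rose in pdp1/2/3, with 10 of 11 called higher (median log2 1.82), among them HB-2, PIL1 and YUC9, a gene of auxin synthesis (log2 3.32, 2.07 and 2.38, adjusted p = 8.9e-07, 7.02e-06 and 4.58e-06). This list and the iron list were drawn up after some of their members were seen, so tests of them as lists restate that. In rrm1 2 of 11 were called, HB-2 and YUC9 (log2 1.31 and 1.13, adjusted p = 0.00106 and 0.00365), and in the quadruple mutant 8. Against pdp1/2/3 the quadruple mutant had 4 of the 11 lower, such as IAA29 (log2 -1.28, adjusted p = 0.00537; 0.0613 without a filter) and PIL1 (log2 -0.86, adjusted p = 0.0141; 0.0695 without pdp1/2/3 replicate 2, 0.0752 and 0.0641 without quadruple-mutant replicate 1 and 2, 0.0893 without a filter, 0.0517 without a trend and 0.108 without rrm1 replicate 1 and quadruple-mutant replicate 1 together). In fve and suvh2/9 limma called 0 of 11 (2 and 0 at an unadjusted p below 0.05). Of 12 iron deficiency genes 3 were called higher in fve and 2 in suvh2/9, and the list passed camera with the preset correlation (adjusted p = 2.37e-06 and 3.9e-09) but neither with an estimated one (0.301 and 0.106) nor by fry (0.307 and 0.172). IRT1 and FRO2 of iron uptake were at log2 1.47 and 1.62 in fve (adjusted p = 0.00752 and 0.00502; 0.122 and 0.0966 without fve replicate 2, 0.169 and 0.153 without a filter, 0.11 and 0.0875 without a trend), and the third, CYP82C4, at 1.725 (adjusted p = 0.0103; 0.0727 without Col-0 replicate 2, 0.152 without fve replicate 2, 0.18 without a filter, 0.117 without a trend). In suvh2/9 FRO2 (log2 1.42, adjusted p = 0.0216) lost its call without a filter (0.447), without a trend (0.293) and with only the groups compared (0.0583), and CYP82C4 (log2 1.62, adjusted p = 0.029) without Col-0 replicate 2 (0.195), suvh2/9 replicate 2 (0.0771), a filter (0.488) or a trend (0.324) and with a mean of at least 5 CPM (0.0597). The Col-0 libraries themselves differed, with IRT1 at 32.9 and 15.5 CPM against 57.1 and 72.3 in fve.

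Touch and wound genes were called higher in each mutant of the second table, 10, 12 and 13 of 13 in rrm1, pdp1/2/3 and the quadruple mutant, but the list did not pass camera with an estimated correlation (adjusted p = 0.129, 0.104 and 0.0859), nor fry in rrm1 (0.0536). The median log2 difference was 1.85 in pdp1/2/3, which was the same after rescaling the libraries and argues against scaling. The mean level of the list separated the 4 libraries that carry pdp1/2/3 from the 4 that do not (difference 1.40 on the log2 scale, exact permutation p = 0.0286, two-sided, the smallest that 70 splits can give). The list was drawn up after such genes were seen to be high in these libraries, so this p decides nothing, and variation between single libraries as the whole cause cannot be told apart. Within all 4 groups the replicates differed in these genes by more than the limits from matched random lists (0.092, 0.119, 0.103 and 0.116), with medians of 0.28 in Col-0, -0.31 in pdp1/2/3, 0.64 in rrm1 and 0.37 in the quadruple mutant. Related genes vary together, and 7, 3, 5 and 4 of 20 other lists passed such limits in Col-0, pdp1/2/3, rrm1 and the quadruple mutant, 2, 2, 0 and 0 of them with a median at least as large. The touch list passing its limits in 4 of 4 groups therefore does not decide, and handling at harvest cannot be told apart from other variation between like plants or from an effect of the genotypes. TCH4, SZF1, TCH3 and the other touch genes called in the mutants are read with that limit. The list of floral repressors outside the FLC clade, which holds TEM1 and TEM2, also differed between the Col-0 replicates, with a median of 0.33 against a limit of 0.108. The rises of TEM1 and TEM2 are read with the same limit.

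The seed storage gene CRA1 was on in the 4 libraries that carry rrm1. In these libraries the median of 7 other seed genes was at most 0.449% of CRA1, which goes against ungerminated seed for those 7. They leave out CRC, the only other seed storage gene above the filter, which was not called. CRC reached 6.43 CPM in rrm1 replicate 2 and 4.56 in quadruple-mutant replicate 1 and was at 0 and 0.000763 in the other 2. A storage gene other than CRA1 was thus seen in 2 of the 4, and ungerminated seed as the source is not decided. Of 8 tested neighbours within 20 kb, 0 were called higher by limma, which argues against a change over the whole neighbourhood. A candidate explanation is derepression of single storage loci in rrm1, which was not tested apart from an insertion or rearrangement at the locus.

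Genes called in fve tended to change the same way in the quadruple mutant, although the tables have separate Col-0 libraries. Of 308 genes called in fve and not in suvh2/9, 160 did so (52.0%), against 13 of 54 called in suvh2/9 and not in fve (24.1%; Fisher's exact test, two-sided, p = 0.00018). This test sets aside the genes called in both and counts the others as independent. Over all calls the share was higher for suvh2/9 than for fve in rrm1 (19.6% against 17.2% higher, 14.3% against 6.12% lower), and genes lower in suvh2/9 were also more often lower in the quadruple mutant (28.6% against 7.16% of all genes), so genes that vary between any libraries cannot be told apart. After removal of the touch, shade and iron lists, 168 of the 169 shared calls were left, but those lists hold only 36 genes tested in both tables, so handling that moved other genes cannot be told apart. Whether FVE and the proteins altered in the quadruple mutant act on part of the same genes, FLC, MAF4 and MAF5 included, was not tested here, and binding or histone marks at the shared genes would be needed to decide it.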
